A study of Chlamydomonas reinhardtii with 12 samples.

How the data were processed

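The 12 RNA libraries of Chlamydomonas reinhardtii were assigned to 6 groups of 2 from the sample labels: 2 strains (the wild type CC-124 and the knockdown line amiCYG12) in 3 incubations (standard, dark aerated for 6 h, anoxia for 6 h). Per the labels' protocols the RNA was selected for poly(A) tails and sequenced with strand information. Base calling with CASAVA 1.8.2, alignment with Bowtie2 2.0.5 and TopHat2 2.0.6, handling with SAMtools 1.2 and quantification with Cufflinks 2.1.1 are stated in the submitters' processing notes. Whether the quantification used the strand, and how reads that match several genes were shared out, is not given in the sources used here.

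The authors deposited 1 table for the series with 19505 transcripts of 17741 loci on genome version 5.5 (Phytozome release 11, per the file headers). For each group of 2 libraries it holds 1 pooled FPKM value (fragments scaled to transcript length and to the mapped total), computed by the authors. For each of 9 comparisons of 2 groups it holds the authors' log2 fold change, a status, a p-value, a q-value and a yes or no for significance. The deposited log2 fold changes equal the log2 of the ratio of the deposited FPKM values to within 5.36e-05. The smallest deposited p-value is 5e-05 and the smallest deposited q-value is 0.000623 in every comparison, and a yes stands at q-values of up to 0.0499; how the authors adjusted the q-values across the comparisons is not given in the sources used here, but a single smallest value points to an adjustment over more than 1 comparison. Of the transcripts 19502 matched a locus tag of the reference annotation of the assembly Chlamydomonas_reinhardtii_v5.5, and 3496 carried a gene symbol in the table. Symbols and descriptions were taken from the table.

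The comparisons, lists of genes, alternatives and the rule for named genes were fixed before the data were examined. The plan foresaw a linear model on values per library and a set test on the same values. Because the table holds group means alone, neither was possible, and this departs from the plan: the calls reported are those of the authors' deposited table, no error between replicates can be given for any value, the depth of each library is unknown, and gene lists are described without a p-value. Totals of FPKM per group do not measure depth. The share of FPKM held by the 100 most abundant transcripts was 64.2, 69.4 and 70.1 percent in the wild type and 61.8, 68.8 and 72.7 percent in amiCYG12.

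Each locus was represented by its most expressed transcript and kept if at least 1 group had 1 FPKM or more, which left 10915 loci, 2800 of them with a symbol. Both steps depart from the plan, which summed the transcripts of a locus and set its minimum of 1 on values per library. A locus counts as called where the authors' deposited table says yes. Log2 values of genes and lists in the text are own values, log2 of the ratio of FPKM plus a pseudocount of 1, except where the authors' deposited table is named and except the strain differences of responses for single genes, which come from the deposited log2 changes without a pseudocount. The called values are large: the smallest absolute deposited log2 fold change among calls lay at 0.861 to 0.890, depending on the comparison.

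The standard error behind each deposited p-value was recovered as the absolute deposited log2 fold change over the matching normal quantile. Its median was 0.352 to 0.356, depending on the comparison, over loci with a mean of at least 10 FPKM in the 2 groups compared. The 5th percentile was 0.339 to 0.341 and the 95th 0.395 to 0.637, so the lower part of the errors differed little between loci. Where errors differ so little, a call depends mainly on the size of the log2 change. The recovered errors describe the authors' p-values and are not replicate errors measured for single genes. At the smallest p-value the recovered error is an upper bound, and above a p-value of 0.95 none was recovered. From these errors the difference of the 2 strains' responses was tested for 3 responses, after the data were seen in this form: the difference of the 2 log2 changes was set over its standard error, the smaller of 2 estimates (from the 2 responses, or from the 2 strain comparisons), compared with a normal distribution, two-sided, and adjusted by Benjamini-Hochberg at 0.05. This was tested on simulated data drawn with normal noise from the recovered errors of the real loci. The simulated p-values used the same errors, 1 per locus for all groups. The false calls below therefore do not cover errors that are wrong in the real data. In the dark response 3, 18, 39 and 42 of 50 changed loci were recovered at true log2 differences of 1, 2, 3 and 4, with 7 false calls among 10294 loci. For the anoxia response the numbers were 2, 19, 37 and 43 with 5 false calls among 10380 loci, and for anoxia against standard 0, 9, 36 and 33 with 7 false calls among 10243. A difference of 1 or 2 would therefore mostly go uncalled.

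Gene lists were written from gene symbols: fermentation and hydrogen metabolism; genes linked to the copper-response regulator; guanylate and adenylate cyclases; cyclic nucleotide phosphodiesterases; truncated hemoglobins; photosystem subunits; light-harvesting antenna; photoprotection; tetrapyrrole and chlorophyll synthesis; Calvin cycle; carbon concentrating mechanism; acetate and glyoxylate; mitochondrial respiratory chain. The others were starch; glycolysis and gluconeogenesis; cytosolic and plastid ribosomal proteins; flagella; nitrogen assimilation; heat shock proteins; proteasome; DNA replication and cell cycle; core histones; antioxidant defence; neutral lipid; gamete genes; and plastid-encoded transcripts. The last list matched 0 loci of the table, so it has no result, and neutral lipid with 3 measured members was too small for a percentile. Each other list's median log2 was set among the medians of 10000 random lists of equal size, matched on mean FPKM in 20 classes. This describes these libraries and gives no p-value. The position is not printed for every list, and a list with several falls and no rises can lie inside the central range. Each list's calls are given over all genes and adjusted over the list alone by Benjamini-Hochberg of the deposited p-values. In simulated shifts of anoxia against dark aerated wild type cells, 9 of 200 unshifted lists of 20 loci fell outside the central range, and 99 of 100 lists shifted by 0.5 were found. The members of these lists were drawn at random from the same loci, so lists whose members vary together were not simulated. Members were matched by symbol alone: the gamete list holds proteasome and nucleotide metabolism genes that carry NSG names, the starch list an alkaline phosphatase, and the neutral lipid list a dehydrogenase.

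Named genes followed the fixed rule, but its demand that the libraries of 2 groups do not overlap could not be applied to pooled values. The rule took CYG12 and the 6 highest and 6 lowest called genes of each comparison. These had to carry a symbol and reach 10 FPKM in the higher group. It also took the 5 at each end of each tested strain difference. Added to these were up to 4 called members of each list (2 where none is called) and a set of genes named in the plan. Of these planned genes LHCSR3 and NIT1 stayed below 1 FPKM in every group and PFR1 did not match a symbol. A few genes chosen only after the values were seen are named as such in the closing section.

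Alternatives planned and run were pseudocounts of 0.1 and 5, no filter on low values, transcripts in place of loci, an added requirement of an absolute log2 fold change of at least 1, and median-ratio rescaling of the 6 groups with p-values recomputed from the recovered errors. Further alternatives were chosen after the data were seen: adjustment within each comparison, a q threshold of 0.01, the recovered errors without rescaling, each of the 2 error estimates alone, summed transcripts, and chromosome 6 left out. Without rescaling, the recovered errors of a comparison give back the deposited p-values. Such counts therefore repeat the adjustment within that comparison, apart from loci without a recovered error, and are no separate model of the error. The rescaling factors were median ratios over 7519 loci, and those of the 2 groups compared differed by -0.13 (wild type, dark aerated against standard), -0.22 (wild type, anoxia against standard), -0.15 and -0.18 (the same 2 in amiCYG12), and by less than 0.1 in the other comparisons; for the rescaled calls this difference was taken off each deposited log2 fold change. Chromosome medians used loci with a mean of at least 5 FPKM. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.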

Results

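The series measured stranded poly(A) RNA by sequencing in the green alga Chlamydomonas reinhardtii, in the wild type CC-124 and in amiCYG12, a transformant carrying an artificial microRNA against the soluble guanylate cyclase gene CYG12. Cultures were sampled in aerated acetate medium under light of 20 µmol photons per square metre per second (standard), or after 6 h of darkness either in open beakers (dark aerated) or in sealed flasks (anoxia). Each of the 6 groups held 2 biological replicates, 12 libraries in all. The dark samples were taken 6 h after the standard ones, and sealed flasks and open beakers also differ in the exchange of other gases. The deposited table gives 1 pooled FPKM value per group, so there are no values per library and no replicate errors to print, and the read depth of each library is unknown. The sum of the FPKM values was 672089, 601731 and 637144 in the wild type (standard, dark aerated, anoxia) and 528786, 515471 and 519823 in amiCYG12. "Rose", "fell", "higher" and "lower" stand for calls of the authors' deposited table at its q threshold of 0.05, over 10915 measured loci; gene values are log2 ratios of the pooled FPKM values after adding 1, except the strain differences of responses in the last 3 paragraphs, which come from the deposited log2 changes without the added 1. FPKM values are printed in the order standard, dark aerated, anoxia.

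The target of the microRNA, CYG12 (Cre07.g320750, chromosome 7, 1168552 to 1174826 of genome version 5.5), had 0.132, 3.23 and 2.46 FPKM in the wild type and 0.158, 0.353 and 0.429 FPKM in amiCYG12. In the authors' deposited table CYG12 was lower in amiCYG12 than in the wild type, with a log2 of -3.19 after the dark aerated incubation and of -2.52 after anoxia, both with a q of 0.000623, and it was not tested in the standard incubation. The wild type itself raised CYG12 in darkness, by a deposited log2 of 4.61 with air and 4.22 without, in the authors' deposited table. The labels of the strains thus matched the level of the target after both dark incubations, while in the standard incubation its level was too low in either strain to check them.

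**Figure D1:**
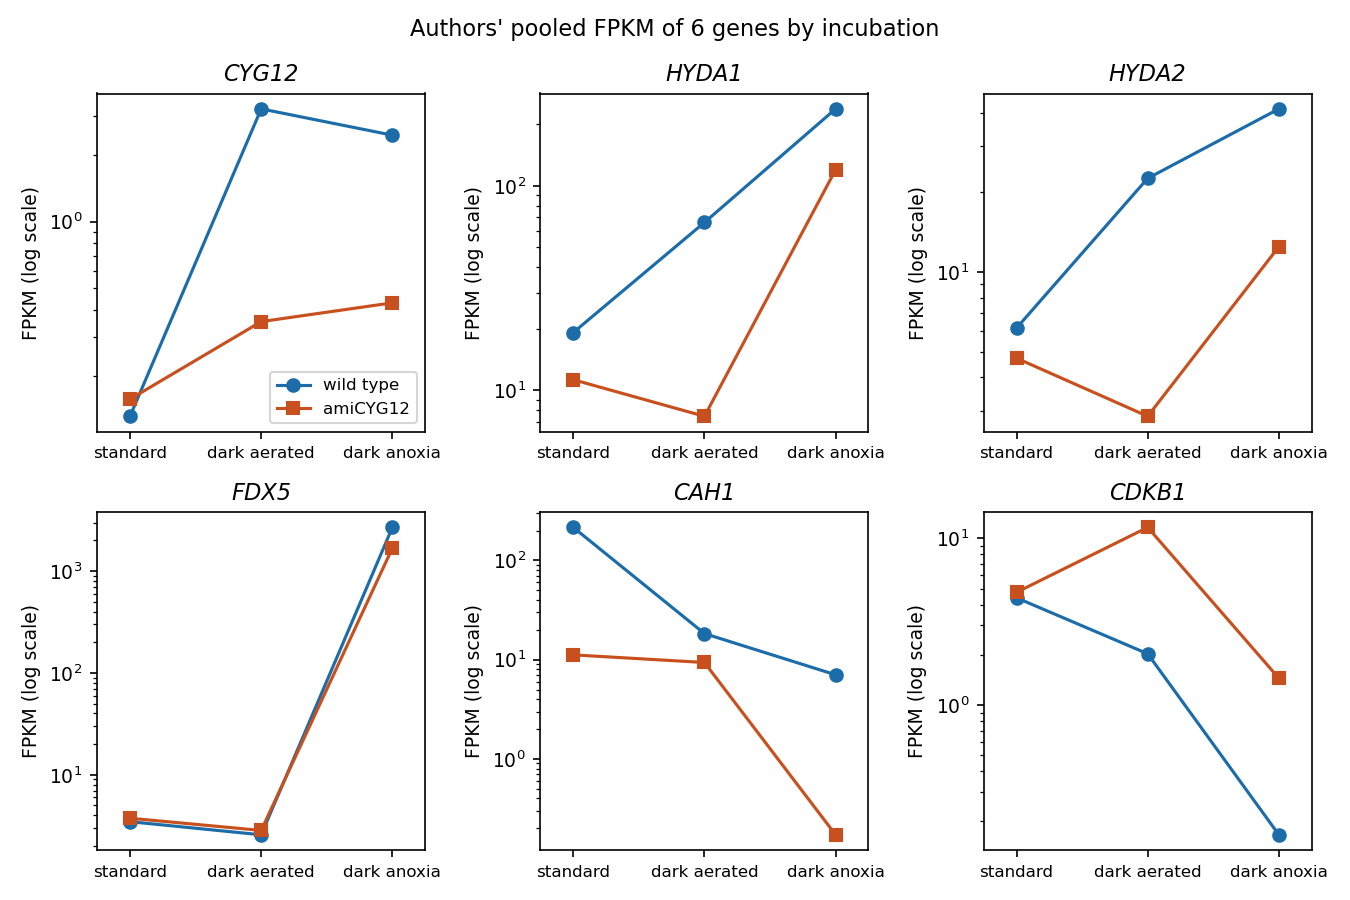
Pooled FPKM (log axis) of CYG12, HYDA1, HYDA2, FDX5, CAH1 and CDKB1 in the 3 incubations, 1 point per group of 2 libraries, wild type as blue circles and amiCYG12 as orange squares. HYDA1 stood at 66.2 FPKM in the wild type and 7.48 in amiCYG12 after the dark aerated incubation, and FDX5 at 2691 and 1684 FPKM under anoxia.

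Which transcripts of the wild type answered to the loss of oxygen in the dark was read from anoxia against the dark aerated incubation. FDX5 (Cre17.g700950), a ferredoxin gene, went from 2.57 to 2691 FPKM, a log2 rise of 9.56. The hydrogenase gene HYDA1 (Cre03.g199800) rose by 1.83 to 238 FPKM, and HYDA2 (Cre09.g396600) had a value of 0.84 that was not called. Other steep rises were those of HPD1, an enzyme of tyrosine breakdown, by 6.06, of the oxidase gene GOX17 by 4.96, of the coproporphyrinogen oxidase CPX1 by 4.00 and of the intramembrane protease RSE1 by 3.97. Cytochrome c6, CYC6, was listed at 0 FPKM in the dark aerated cells and at 50.7 FPKM under anoxia. The deepest falls were in CTH1, -3.53, the partner of the chlorophyll synthesis gene CRD1, in the transaldolase TAL1, -3.24, in the methionine synthase METE, -3.15, in the septin SEP1, -2.99, in SHMT2, -2.89, and in the citrate synthase CIS2, -2.82. Of 10697 tested loci 1587 were called, 736 higher and 851 lower.

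Fermentation and hydrogen metabolism went up as a group: of 20 measured members 9 rose and 0 fell (10 and 0 adjusted over the list alone), and its median of 0.85 lay above all 10000 random lists. The hydrogenase maturases HYDG and HYDEF rose by 0.91 and 1.49, the pyruvate formate lyase PFL1 by 1.24, and all 4 genes of hybrid-cluster proteins rose, from 0.85 for HCP2 to 2.74 for HCP4. The alcohol dehydrogenase ADH1 had a value of -0.57 and was not called. In the group linked to the copper-response regulator, of 10 measured members 7 rose and 1 fell (the same adjusted over the list alone). The transporters CTR2 and CTR3 rose by 2.48 and 2.70 and CRD1 by 3.09, while CTH1 alone fell. Proteasome subunits moved the other way, with a median of -1.27: of 15 measured members 0 rose and 13 fell (0 and 14 adjusted over the list alone), RPN8 with -1.64 and RPN12 with -1.55. In the acetate and glyoxylate list, of 9 measured members 1 rose and 6 fell (1 and 7 adjusted over the list alone), among them the aconitase ACH1 with -2.33 and the acetyl-CoA synthetase ACS3 with -2.30, against a rise of 1.43 in ACS1. Of the glycolysis list's 17 measured members 2 rose and 8 fell (the same adjusted over the list alone), with GAP1 at -1.63 and the pyruvate phosphate dikinase PPD1 at 2.33.

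In the respiratory chain, of 71 measured members 2 rose and 9 fell (2 and 8 adjusted over the list alone). The alternative oxidase AOX2 rose by 2.67 while the complex II and III subunits SDH3 and QCR8 fell, with -1.56 and -1.55. Among antioxidant genes, of 18 measured members 1 rose and 8 fell (1 and 10 adjusted over the list alone), with the glutathione peroxidase GPX5 at -2.10 and the catalase CAT2 at 1.52. Of the replication and cell cycle list's 20 measured members 1 rose and 8 fell (1 and 9 adjusted over the list alone), among them the sliding clamp gene PCN1 with -1.80 and the mitotic kinase CDKB1 with -1.38. In the list named for gametes, of 12 measured members 1 rose and 9 fell (the same adjusted over the list alone), but the members that fell include proteasome subunits (RPT4/NSG8, -1.61) and a ribonucleotide reductase (RIR2A/NSG2, -1.66), which serve protein breakdown and DNA synthesis in any cell. Starch genes split: of 16 measured members 3 rose and 5 fell (4 and 5 adjusted over the list alone), including the branching enzyme SBE3 with 1.15 and the synthase SSS1 with -1.31. The list's PHO1 is described in the table as an alkaline phosphatase. Nucleotide cyclases make cyclic nucleotides and phosphodiesterases break them. Of the cyclases' 36 measured members 7 rose and 3 fell (the same adjusted over the list alone). Of the phosphodiesterases' 20 measured members 5 rose and 1 fell (the same adjusted over the list alone), PDE22 among them with 1.18. Photosystem subunits hardly moved here, since of 20 measured members 1 rose and 1 fell (0 and 0 adjusted over the list alone), and cytosolic ribosomal proteins had 0.18 as their median with 1 of 70 rising and 0 called adjusted over the list alone. With the recovered errors, which return the deposited p-values adjusted within this comparison, 595 loci were called higher and 679 lower. Rescaling to a common median ratio in addition gave 732 higher and 551 lower.

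The effect of 6 h of darkness with air on the wild type came from dark aerated against standard cells. Genes of the light reactions, of chlorophyll synthesis and of plastid translation decreased together, while several genes of hydrogen metabolism increased although the beakers were open. HYDA1 rose by 1.74, HYDA2 by 1.72 and HYDG by 1.97. Other genes that rose were the low-CO2-inducible LCI34 (Cre03.g191300) with 3.51, the clock gene ROC40 with 3.49 and the cell wall genes HRP3 and PHC8 with 2.26 and 2.07. A neighbouring LCI34 locus (Cre03.g191250) rose by 1.91, and reads shared between the 2 cannot be excluded. The periplasmic carbonic anhydrase CAH1 fell from 216 to 18.3 FPKM, a log2 of -3.49. Further falls were those of the clock gene ROC59 with -3.00, the superoxide dismutase MSD3 with -2.97, the thiamine synthesis gene THI4 with -2.72, METE with -2.55 and BCS1, a factor for building the cytochrome bc1 complex, with -2.35. Of 10607 tested loci 1170 were called, 454 higher and 716 lower.

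Of the photosystem list's 20 measured members 0 rose and 19 fell (the same adjusted over the list alone), with PSAN at -1.58 and PSBY2 at -1.58. Light-harvesting antenna genes, many of them near-identical copies whose reads cannot be told apart with certainty, had a median of -1.53: of 21 measured members 0 rose and 19 fell (0 and 20 adjusted over the list alone), LHCA4 with -2.02. Tetrapyrrole synthesis followed, since of 18 measured members 0 rose and 15 fell (0 and 16 adjusted over the list alone), among them UPD2/UROD2 with -2.08 and GSA1, an enzyme of its early steps, with -1.80. Plastid ribosomal proteins had a median of -0.96, and of 35 measured members 0 rose and 23 fell (0 and 35 adjusted over the list alone). Cytosolic ribosomal proteins stood apart from them with 0.10 as their median and none of the 70 called. Of the Calvin cycle list's 14 measured members 1 rose and 5 fell (the same adjusted over the list alone), with RBCS1 at -1.69, PGK1 at -1.37 and PRK1 at -1.34. In the carbon concentrating mechanism, of 12 measured members 0 rose and 6 fell (0 and 9 adjusted over the list alone), among them CAH5 with -1.58 and LCIB with -1.19. Among heat shock proteins, of 19 measured members 1 rose and 6 fell (the same adjusted over the list alone), HSP90B at -1.35. Among antioxidant genes, of 18 measured members 0 rose and 8 fell (the same adjusted over the list alone), PRX6 at -1.74.

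Fermentation genes had a median of 0.34, above all 10000 random lists: of 20 measured members 7 rose and 0 fell (the same adjusted over the list alone), HCP4 with 1.99, HCP1 with 1.49 and HYDEF with 0.96. In the copper-linked group, of 10 measured members 0 rose and 4 fell (the same adjusted over the list alone), CTH1 with -1.73 and CPX1 with -1.48. Its median of -0.62 lay inside the central range of the random lists. In the cyclase list, of 36 measured members 4 rose and 1 fell (the same adjusted over the list alone). Among truncated hemoglobins, small heme proteins that bind oxygen or nitric oxide, of 9 measured members 2 rose and 0 fell (the same adjusted over the list alone). THB7 rose by 1.40 and THB12 by 0.81. THB8 went from 0.0107 to 35.5 FPKM but had a q of 0.320 in the authors' deposited table and was not called. Of the neutral lipid list's 3 measured members 2 rose and 0 fell (the same adjusted over the list alone): the lipid droplet protein gene MLD1/MLDP1 rose by 1.64 and the acyltransferase DGTT1 by 0.58, while its PGD1 is described in the table as a dehydrogenase of serine synthesis. The respiratory chain, the acetate list and the proteasome had 0 members called in either direction, whether or not adjusted over the list alone. Flagella genes had -0.18 as their median, and of 279 measured members 1 rose and 24 fell (1 and 4 adjusted over the list alone). With the recovered errors the calls numbered 780, 316 higher and 464 lower, and with rescaling added 707, 420 higher and 287 lower. The excess of falls thus rests on the authors' scale, the rescaling factors of the 2 groups differing by -0.13; the medians of the photosystem, antenna, tetrapyrrole and plastid ribosome lists lie far beyond that shift.

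Darkness and anoxia together were read in the wild type from anoxia against the standard incubation. FDX5 again led with 9.24, followed by HPD1 with 5.85, CYC6 with 5.53, the hybrid-cluster protein gene HCP4 with 4.73, GOX17 with 4.33 and RSE1 with 4.25. METE dropped from 308 to 4.95 FPKM, a log2 of -5.70, and CTH1 from 339 to 7.86, a log2 of -5.26. The genes of the iron-assimilating proteins FEA1 and FEA2 fell with values of -4.90 and -4.25, CAH1 with -4.75 and MSD3 with -4.21. Of 10739 tested loci 2940 were called, 1233 higher and 1707 lower.

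Fermentation genes were up here too: of 20 measured members 12 rose and 2 fell (the same adjusted over the list alone), with HYDA1 at 3.56 and HYDG at 2.88. In the copper-linked group, of 10 measured members 7 rose and 2 fell (the same adjusted over the list alone). Photosystem subunits and antenna genes had medians of -1.51 and -1.48. Of the photosystem list's 20 measured members 0 rose and 16 fell (0 and 17 adjusted over the list alone). Of the antenna list's 21 measured members 1 rose and 17 fell (1 and 18 adjusted over the list alone). In tetrapyrrole synthesis, of 18 measured members 3 rose and 14 fell (the same adjusted over the list alone), the members that rose including CPX1 with 2.53 and CRD1 with 2.05. Of the antioxidant list's 18 measured members 1 rose and 12 fell (1 and 13 adjusted over the list alone), and of the proteasome list's 15 measured members 0 rose and 13 fell (0 and 14 adjusted over the list alone). Heat shock proteins had a median of -0.74, and of 19 measured members 1 rose and 9 fell (the same adjusted over the list alone), HSP70C among the falls with -3.31. In the carbon concentrating mechanism, of 12 measured members 0 rose and 8 fell (1 and 9 adjusted over the list alone); in the plastid ribosome, of 35 measured members 0 rose and 6 fell (0 and 5 adjusted over the list alone). Of the flagella list's 279 measured members 11 rose and 17 fell (7 and 11 adjusted over the list alone); its median was -0.051 on the authors' scale and 0.13 after rescaling, so no direction can be given for it. With the recovered errors 1281 were called higher and 1785 lower, and with rescaling added 1832 and 1294, the rescaling factors differing by -0.22.

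The same contrast of anoxia and dark aerated cells in amiCYG12 asked which of the responses to oxygen loss the knockdown line still made. FDX5 rose by 8.78 to 1684 FPKM, GOX17 by 6.51, HPD1 by 5.70, and 2 further oxidase genes of the GOX family, GOX8 and GOX7, by 4.45 and 4.01. HYDA1 rose from 7.48 to 119.8 FPKM, a log2 of 3.83, and HYDA2 by 1.81. The deepest falls were in the flagellar protein gene FAP211, -4.34, in SEP1, -3.32, in the phosphoglucomutase GPM1, -3.18, in the chaperonin CPN60C, -3.10, and in the pyrophosphatase IPY3, -3.00. Of 10768 tested loci 2775 were called, 1390 higher and 1385 lower (1439 and 1437 with the recovered errors, 1536 and 1350 with rescaling added). The wild type and amiCYG12 shared 418 loci called higher in this response, where 92.4 would be shared if the 2 sets were independent, and 528 called lower against 102, while 7 loci were called in opposite directions.

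Of the flagella list's 279 measured members 165 rose and 7 fell (192 and 9 adjusted over the list alone), with a median of 0.86, above all 10000 random lists. This rise set out from the low level of the dark aerated group, since against the standard incubation the median was -0.22. FAP138 rose by 2.97, FAP113 by 2.53 and FAP292 by 2.46. Fermentation genes had a median of 1.02: of 20 measured members 11 rose and 1 fell (the same adjusted over the list alone), HCP3 with 3.40 and HYDEF with 2.59. The copper-linked group responded as well, since of 10 measured members 6 rose and 1 fell (the same adjusted over the list alone), CRD1 with 3.06 and CTR3 with 2.40. More cyclases and phosphodiesterases rose than fell: of the cyclases' 36 measured members 13 rose and 2 fell (15 and 2 adjusted over the list alone). Of the phosphodiesterases' 20 measured members 9 rose and 0 fell (10 and 1 adjusted over the list alone). Of the antenna list's 21 measured members 0 rose and 15 fell (the same adjusted over the list alone), CP29/LHCB4 with -1.81, and of the tetrapyrrole list's 18 measured members 2 rose and 13 fell (2 and 14 adjusted over the list alone), PPX1 with -2.56. In the carbon concentrating mechanism, of 12 measured members 0 rose and 9 fell (the same adjusted over the list alone), CAH1 with -3.15 and LCIB with -2.83. Cell cycle genes had a median of -0.94, and of 20 measured members 1 rose and 13 fell (1 and 14 adjusted over the list alone), CDKB1 with -2.37; against the standard incubation their median was -0.22. Of the proteasome list's 15 measured members 0 rose and 12 fell (the same adjusted over the list alone), and of the acetate list's 9 measured members 1 rose and 6 fell (1 and 7 adjusted over the list alone), ACS3 with -2.87.

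In amiCYG12 the dark aerated incubation, set against the standard one, lowered flagella genes and raised genes of the cell cycle. METE fell the most, with -4.04, followed by the antenna gene LHCBM9 with -2.54, CAM9 with -2.36, the flagellar genes FAP285/FAP170 and RSP23 with -2.26 and -2.21, and LHCBM7 with -2.13. ROC40 rose by 3.30, the low-CO2-inducible LCI30 by 1.95, the plastid division gene MIND1 by 1.37, PPR9 by 1.34, CDKB1 by 1.14 and the ribonucleotide reductase RIR2A/NSG2 by 1.11. The hydrogenase genes HYDA1, HYDA2 and HYDG had log2 values of -0.54, -0.57 and -0.46 without a call. Of 10619 tested loci 1478 were called, 439 higher and 1039 lower. Between the strains 86 loci rose in this response in both, against 14.0 if independent, 248 fell in both, against 70.2, and 25 were called in opposite directions.

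Of the flagella list's 279 measured members 3 rose and 202 fell (6 and 229 adjusted over the list alone), with a median of -1.08, below all 10000 random lists. FAP138, FAP7 and FAP32, an intraflagellar transport protein gene, had values of -2.18, -2.13 and -2.00. In the replication and cell cycle list, of 20 measured members 10 rose and 0 fell (12 and 0 adjusted over the list alone), with the cyclins CYCA1 and CYCB1 at 1.39 and 1.31 and the replication helicase genes MCM3 and MCM4 at 1.23 and 0.98. Photosystem subunits had a median of -1.03 and antenna genes of -1.28: of the first list's 20 measured members 0 rose and 12 fell (0 and 14 adjusted over the list alone), and of the second list's 21 measured members 0 rose and 18 fell (0 and 19 adjusted over the list alone). In tetrapyrrole synthesis, of 18 measured members 0 rose and 3 fell (the same adjusted over the list alone); in the plastid ribosome, of 35 measured members 0 rose and 2 fell (0 and 1 adjusted over the list alone). Among fermentation genes, of 20 measured members 0 rose and 3 fell (the same adjusted over the list alone); the 3 falls were those of ADH1 with -0.93, the phosphate acetyltransferase PAT2 with -0.83 and HCP3 with -0.81. In the carbon concentrating mechanism none of 12 was called and the median was 0.064. Of the antioxidant list's 18 measured members 0 rose and 7 fell (the same adjusted over the list alone), PRX1 with -1.62; of the gamete list's 12 measured members 4 rose and 1 fell (the same adjusted over the list alone), RIR2A/NSG2 among the rises. With the recovered errors 335 loci were called higher and 873 lower, and with rescaling added 480 and 617, the rescaling factors differing by -0.15.

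Anoxia against the standard incubation in amiCYG12 gave FDX5 a rise of 8.47, GOX17 of 5.82, HPD1 of 5.33, GOX8 of 4.54, ROC40 of 4.21 and GOX7 of 3.89. The lowest values were those of METE with -5.33, GPM1 with -5.03, FEA1 with -4.79, FAP211 with -4.62, GST10, named as a glutathione transferase, with -4.33, and LHCBM9 with -4.29. HYDA1 reached 3.30 and HCP3 2.59. Of 10739 tested loci 2676 were called, 995 higher and 1681 lower. With the wild type 659 of the rises and 1140 of the falls were shared, against 110 and 266 if independent, and 12 loci were called in opposite directions.

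Every antenna gene fell in this contrast: of 21 measured members 0 rose and 21 fell (the same adjusted over the list alone), with a median of -2.39, and of the photosystem list's 20 measured members 0 rose and 19 fell (the same adjusted over the list alone), PSAI with -2.62. Plastid ribosomal proteins had a median of -0.90, just inside the central range of the random lists. Of 35 measured members 0 rose and 18 fell (0 and 27 adjusted over the list alone). Of the Calvin cycle list's 14 measured members 0 rose and 7 fell (the same adjusted over the list alone), PGK1 with -3.74 and FBP1 with -2.44. Glycolysis had a median of -1.22: of 17 measured members 0 rose and 10 fell (0 and 11 adjusted over the list alone). Proteasome genes had a median of -1.80, and of 15 measured members 0 rose and 14 fell (the same adjusted over the list alone); of the heat shock list's 19 measured members 1 rose and 10 fell (the same adjusted over the list alone), HSP70C with -3.56. Of the acetate list's 9 measured members 1 rose and 7 fell (1 and 8 adjusted over the list alone), ACS3 with -3.04; of the starch list's 16 measured members 0 rose and 6 fell (the same adjusted over the list alone). In the nitrogen assimilation list, of 12 measured members 0 rose and 5 fell (the same adjusted over the list alone). In the flagella list, of 279 measured members 5 rose and 20 fell (3 and 11 adjusted over the list alone). The medians of the Calvin cycle, starch, nitrogen assimilation and flagella lists all lay inside the central range of the random lists. Among fermentation genes, of 20 measured members 8 rose and 3 fell (9 and 4 adjusted over the list alone), and of the copper-linked group's 10 measured members 6 rose and 2 fell (the same adjusted over the list alone). With the recovered errors 1020 were called higher and 1720 lower, and with rescaling added 1422 and 1270, the rescaling factors differing by -0.18.

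**Figure D2:**
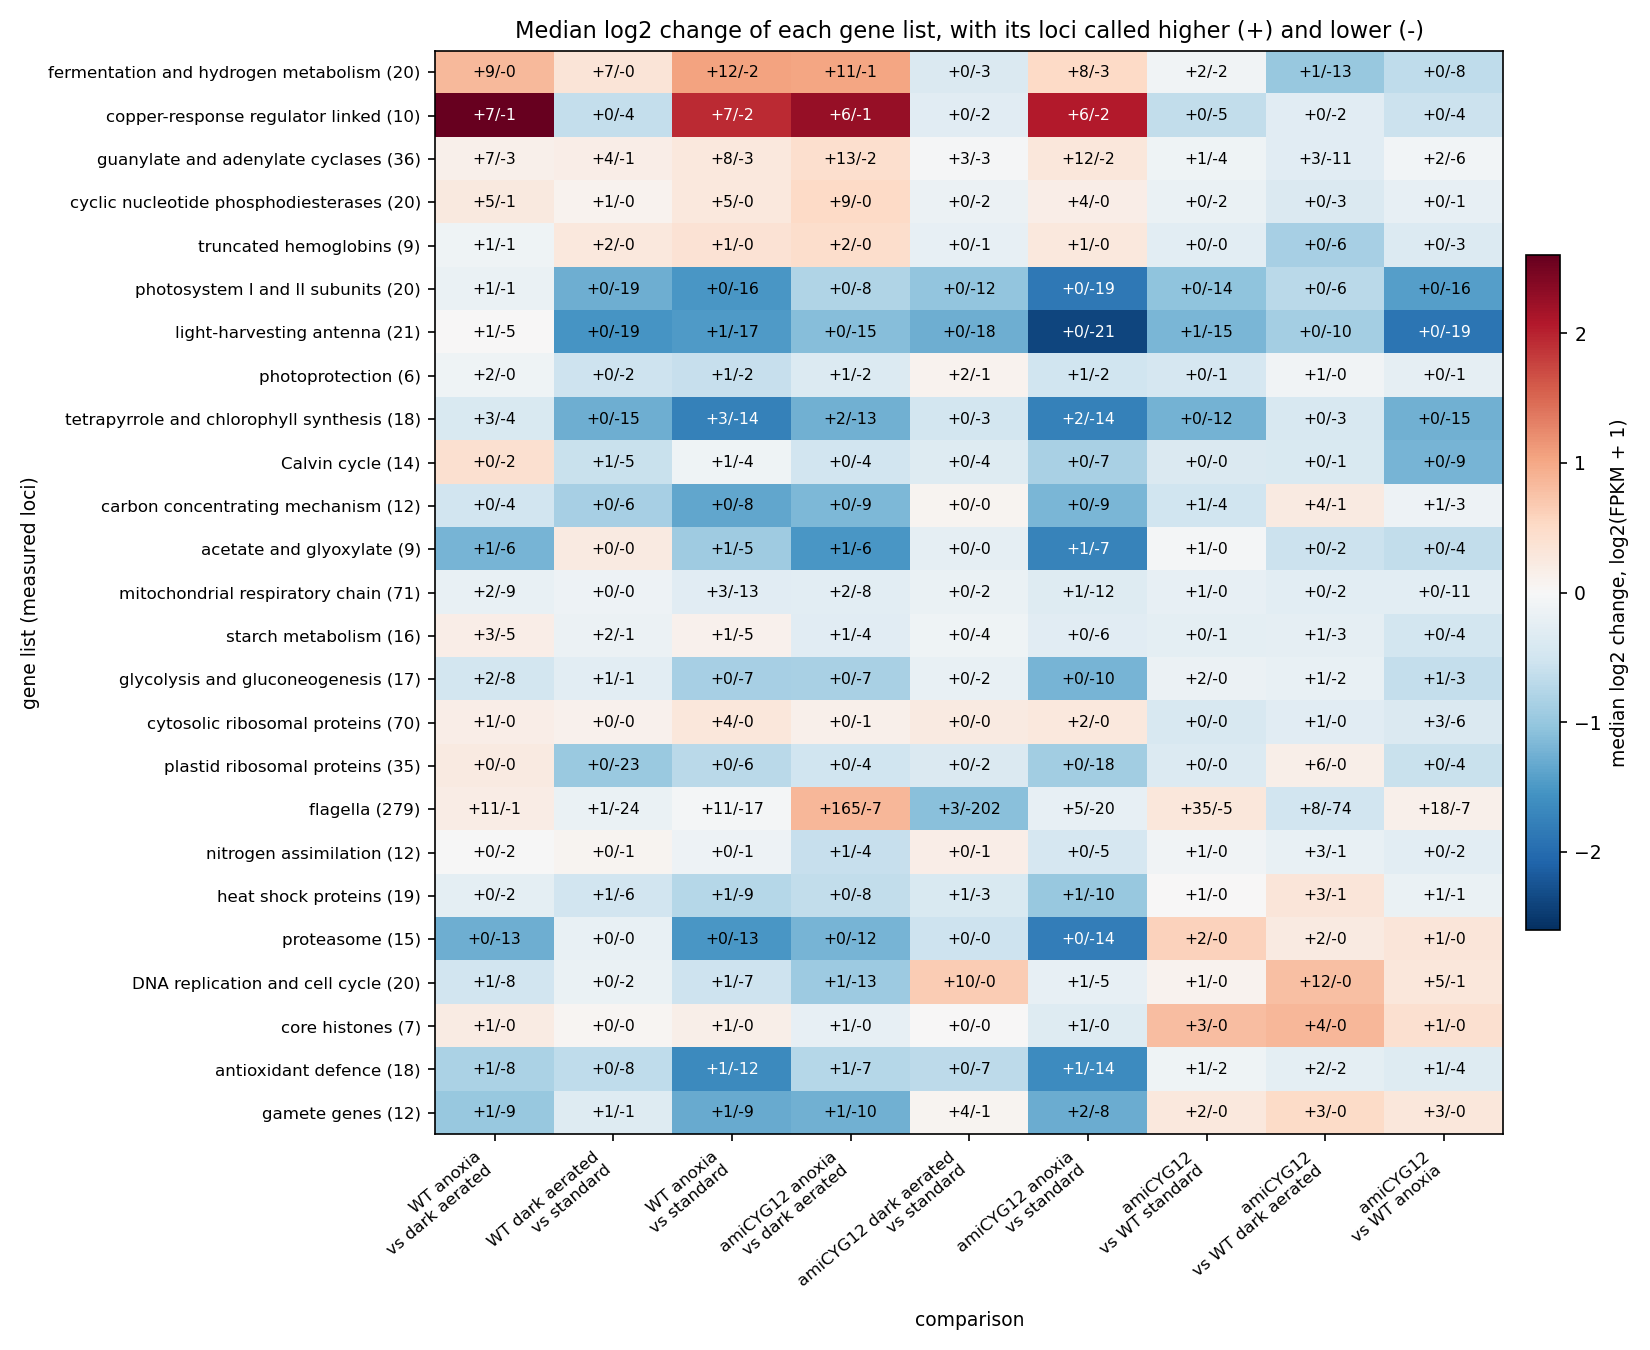
Median log2 change of 25 gene lists (rows) in the 9 comparisons (columns), as colour, with the number of members called higher (+) and lower (-) printed in each cell. Flagella genes had medians of -1.08 in amiCYG12 from standard to dark aerated and 0.86 from dark aerated to anoxia, against -0.18 and 0.19 in the wild type.

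The strains were first compared in the standard incubation, where CYG12 itself was near 0 in both. FAP211 was higher in amiCYG12 by 3.55, ADH5, named as an alcohol dehydrogenase, by 2.31, MMP29, named as a metalloprotease, by 1.89, and 3 genes of chromosome 6, the UDP-glucose dehydrogenase UGD2, the proteasome subunit RPN8 and UAA3, by 1.87, 1.78 and 1.72. The cell wall protein gene PHC18 was lower in amiCYG12, with a log2 of -4.88, CAH1 of -4.15, the autophagy gene APG10 of -3.89, the cytochrome P450 CYP1/CYP747A1 of -2.91, MSD3 of -2.84 and the protochlorophyllide reductase POR1 of -2.80. Of 10548 tested loci 1111 were called, 579 higher and 532 lower in amiCYG12, and 408 of the 579 higher ones lay on chromosome 6. Without that chromosome 690 calls remained, 171 higher and 519 lower. On all chromosomes together the recovered errors gave 356 higher and 340 lower, and rescaling in addition 413 and 302.

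Chromosome 6 as a whole stood above the rest of the genome in amiCYG12: its 496 loci with a mean of at least 5 FPKM had a median log2 difference of 0.73 in the standard, 0.76 in the dark aerated and 0.71 in the anoxic incubation, against -0.18, -0.18 and -0.14 over 3732 loci of the other chromosomes. The distance was 0.90, 0.93 and 0.85, which corresponds to ratios of 1.87, 1.91 and 1.8. Strain differences of single chromosome 6 genes were not corrected for this common shift.

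**Figure D3:**
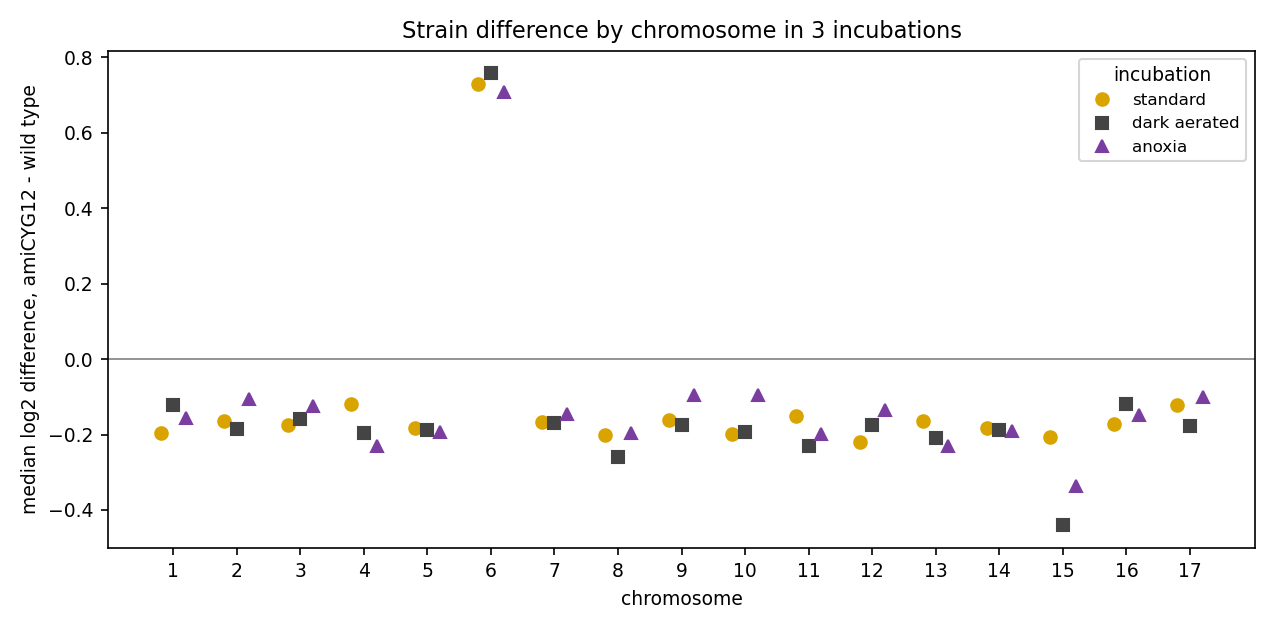
Median log2 difference of amiCYG12 and the wild type per chromosome (1 to 17, horizontal axis) over loci with a mean of at least 5 FPKM, 1 point per incubation. Chromosome 6 lies at 0.73, 0.76 and 0.71, and every other chromosome lies below 0.

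In the standard incubation many antenna and photosystem genes were lower in amiCYG12. Of the antenna list's 21 measured members 1 was higher and 15 lower (1 and 16 adjusted over the list alone), with a median of -1.18 and of -1.27 without chromosome 6, LHCBM7 at -1.85 and LHCA4 at -1.84. Of the photosystem list's 20 measured members 0 were higher and 14 lower (0 and 17 adjusted over the list alone), PSBY2 at -1.52 and PSAH at -1.33. In tetrapyrrole synthesis, of 18 measured members 0 were higher and 12 lower (0 and 13 adjusted over the list alone), PBGD1 at -2.10 and GSA1 at -1.93. None of the 14 Calvin cycle genes and none of the 35 plastid ribosomal protein genes was called, with medians of -0.37 and -0.35. Of the carbon concentrating list's 12 measured members 1 was higher and 4 lower (1 and 5 adjusted over the list alone), among them LCI1 with -2.58 and the mitochondrial carbonic anhydrase CAH4 with -2.51. In the copper-linked group, of 10 measured members 0 were higher and 5 lower (the same adjusted over the list alone), CTH1 at -1.78, CPX1 at -1.57 and CRD1 at -1.36. Fermentation genes split here: of 20 measured members 2 were higher and 2 lower (1 and 2 adjusted over the list alone). HYDG and HYDEF were higher by 0.96 and 0.56 on chromosome 6, HCP2 and HCP3 lower with -0.97 and -0.78. In the flagella list, of 279 measured members 35 were higher and 5 lower (30 and 5 adjusted over the list alone), and 16 of the higher members lay off chromosome 6. Core histones, whose near-identical copies and poly(A) selection make any value uncertain, had a median of 0.81: of 7 measured members 3 were higher and 0 lower (4 and 0 adjusted over the list alone), HTA37 at 1.18. In the photoprotection list, of 6 measured members 0 were higher and 1 lower (1 and 1 adjusted over the list alone). Cytosolic ribosomal proteins had a median of -0.41 with none called.

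After the dark aerated incubation the strains differed most, and the hydrogen metabolism genes that had risen in the wild type were low in amiCYG12. HYDA1 was lower in amiCYG12, with a log2 of -2.99, HYDA2 of -2.61, HCP3 of -2.50, and PFL1 of -0.99. The truncated hemoglobin THB8 stood at 35.5 FPKM in the wild type and 0.333 in amiCYG12, a log2 of -4.78. PHC18 was lower, with -6.41, the ion channel gene TRP5 with -3.71, LCI34 (Cre03.g191300) with -3.36 and APG10 with -3.21. Higher in amiCYG12 were FAP211 by 4.05, ADH5 by 2.61, CDKB1 by 2.06, and on chromosome 6 UAA3 by 2.45, UGD2 by 2.17 and EZY7 by 1.99. Of 10758 tested loci 2048 were called, 882 higher and 1166 lower. On chromosome 6 lay 467 of the higher ones, and without it 415 were higher and 1133 lower. The recovered errors gave 809 higher and 1094 lower on all chromosomes together, and rescaling in addition 951 and 937. These totals include the raised loci of chromosome 6, and the rescaling factors differed by -0.07. Rescaled calls were not counted without chromosome 6, so whether the excess of lower calls off it depends on the scale was not tested.

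Of the fermentation list's 20 measured members 1 was higher and 13 lower (the same adjusted over the list alone), with a median of -0.99, below all 10000 random lists. ADH1 was at -1.09, HCP4 at -2.02 and HCP1 at -1.52. Among the truncated hemoglobins, of 9 measured members 0 were higher and 6 lower (0 and 8 adjusted over the list alone), THB7 at -2.05, THB10 at -1.14 and THB11 at -1.05. In the cyclase list, of 36 measured members 3 were higher and 11 lower (4 and 11 adjusted over the list alone), CYG12 among the lower ones, and of the phosphodiesterase list's 20 measured members 0 were higher and 3 lower (0 and 2 adjusted over the list alone). Cell cycle genes were higher: of 20 measured members 12 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 0.77, CYCA1 at 1.93, CYCB1 at 1.89 and MCM3, on chromosome 6, at 2.00. Of the flagella list's 279 measured members 8 were higher and 74 lower (9 and 89 adjusted over the list alone), with a median of -0.50, FAP15 at -2.35. In the antenna list, of 21 measured members 0 were higher and 10 lower (0 and 12 adjusted over the list alone), and in the photosystem list, of 20 measured members 0 were higher and 6 lower (0 and 7 adjusted over the list alone). Of the plastid ribosome list's 35 measured members 6 were higher and 0 lower (the same adjusted over the list alone), and all 6 higher members, PRPL29 among them with 1.50, lay on chromosome 6. In the carbon concentrating mechanism, of 12 measured members 4 were higher and 1 lower (4 and 3 adjusted over the list alone), LCIC on chromosome 6 at 1.72 and CAH4 at -1.66. Of the nitrogen assimilation list's 12 measured members 3 were higher and 1 lower (4 and 2 adjusted over the list alone), and of the neutral lipid list's 3 measured members 0 were higher and 2 lower (the same adjusted over the list alone).

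Under anoxia LAL2, an RNA-binding protein gene, was higher in amiCYG12 by 2.35, GOX8 by 1.95, the cell wall gene GAS28 by 1.78, MMP9 by 2.1, and on chromosome 6 TSD2 by 1.79 and PRL8 by 1.8. PHC18 was lower in amiCYG12, with a log2 of -5.94, THB8 of -4.53, LHCBM9 of -4.02, the lipase and flagellar gene TGL15/FAP199 of -3.31, LHCA5 of -3.08 and POR1 of -3.00. HYDA1 was still lower, with a log2 of -0.98, with 238 FPKM in the wild type and 119.8 in amiCYG12. Of 10669 tested loci 1585 were called, 611 higher and 974 lower; 404 of the higher ones lay on chromosome 6, and without it 207 were higher and 943 lower. The recovered errors gave 503 higher and 821 lower, and rescaling in addition 521 and 790.

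Of the antenna list's 21 measured members 0 were higher and 19 lower (the same adjusted over the list alone), with a median of -1.90, LHCBM7 at -2.71 and LHCA3 at -2.56. Of the photosystem list's 20 measured members 0 were higher and 16 lower (the same adjusted over the list alone), with a median of -1.43, PSAI at -2.69 and PSAK at -2.34. In tetrapyrrole synthesis, of 18 measured members 0 were higher and 15 lower (the same adjusted over the list alone), UPD1/HEME/UROD1 at -2.09. The Calvin cycle had a median of -1.20: of 14 measured members 0 were higher and 9 lower (0 and 10 adjusted over the list alone), PGK1 at -2.22, PRK1 at -1.92 and FBP1 at -1.82. In the fermentation list, of 20 measured members 0 were higher and 8 lower (0 and 9 adjusted over the list alone), HCP4 at -3.00, HCP1 at -2.17 and HYDA2 at -1.65. Of the copper-linked group's 10 measured members 0 were higher and 4 lower (the same adjusted over the list alone), CYC6 at -2.11 and CPX1 at -1.66. The respiratory chain had a median of -0.27, inside the central range of the random lists, -0.44 to -0.071. Of its 71 measured members 0 were higher and 11 lower (0 and 10 adjusted over the list alone). Among the lower ones were the mitochondrial ATP synthase subunits ATP5 with -1.41 and ATP1A with -1.36. Of the truncated hemoglobins' 9 measured members 0 were higher and 3 lower (the same adjusted over the list alone). In the starch list, of 16 measured members 0 were higher and 4 lower (0 and 5 adjusted over the list alone), AGP1/STA1, a subunit of the enzyme that makes ADP-glucose, at -1.60. Of the cytosolic ribosomal proteins' 70 measured members 3 were higher and 6 lower (2 and 6 adjusted over the list alone), and all 3 higher members lay on chromosome 6. In all 3 incubations together 151 loci were higher in amiCYG12 and 173 lower, against 2.30 and 4.57 if the 3 sets were independent.

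Whether the strains differed in their dark response was tested as the difference of the 2 log2 changes from standard to dark aerated, with a standard error recovered from the authors' p-values. These gene values carry no added 1 and are larger at low levels: for 90 of the 227 loci called here they exceeded the difference of the values with the added 1 by over 1.5 times, and for 0 the sign turned. CYCA1, for example, had 2.18 with the added 1. Medians of lists include the added 1. Of 10539 loci 227 differed, 87 upward and 140 downward in amiCYG12. The responses of HYDA1, HYDA2 and HYDG differed by -2.38 (standard error 0.566, q 0.00640), -2.61 (standard error 0.590, q 0.00382) and -2.59 (standard error 0.530, q 0.000666). CAH1 differed by 3.30 (standard error 0.966, q 0.0390), since it fell in the wild type from 216 to 18.3 FPKM and stood at 11.2 and 9.37 FPKM in amiCYG12. The carbon uptake genes LCIA/NAR1.2 and LCIC differed by 3.27 and 1.71, BCS1 by 3.09, ROC59 by 2.50, and LCI34 (Cre03.g191300) by -4.04 (standard error 1.04, q 0.0133). Of the fermentation list's 20 members 0 differed upward in amiCYG12 and 5 downward (0 and 9 adjusted over the list alone), HCP3 with -3.00 and HYDEF with -2.19. Of the flagella list's 279 members 0 differed upward in amiCYG12 and 25 downward (0 and 89 adjusted over the list alone), FAP138 with -3.58, and the median was -0.85. In the cell cycle list, of 20 members 4 differed upward in amiCYG12 and 0 downward (11 and 0 adjusted over the list alone), CYCA1 with 2.98, CYCB1 with 2.61, CDKB1 with 2.41 and MCM3 with 2.17. For the carbon concentrating mechanism, of 12 members 3 differed upward in amiCYG12 and 0 downward (6 and 0 adjusted over the list alone). Tetrapyrrole synthesis had a median difference of 0.83, above all 10000 random lists, and plastid ribosomal proteins of 0.56, with no single member called. With the spread taken from the 2 strain comparisons alone 114 loci remained.

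The response to oxygen loss, from dark aerated to anoxia, differed between the strains at 75 of 10673 loci, 33 upward and 42 downward in amiCYG12, and 25 of the 75 exceeded the difference with the added 1 by over 1.5 times. The dark aerated groups enter this response and the dark response alike: 72 of the 75 loci had a dark response difference of the opposite sign, which was called for 16, and of these 16 none was called from standard to anoxia. LHCBM9 differed by -5.00 (standard error 0.873, q 0.000106): its values were 14.9, 5.79 and 34.8 FPKM in the wild type, while in amiCYG12 it went from 6.43 to 1.2 FPKM. Its near-identical neighbours make the assignment of its reads uncertain. PSAI, a photosystem I subunit, differed by -2.48 (standard error 0.528, q 0.00451), LHCA3 by -2.14, and the mitochondrial ribosome gene MRPS29/CPL4 by -2.93 (standard error 0.627, q 0.00451). TRP5 differed upward by 3.76 (standard error 1.04, q 0.0455), FAP138 by 2.28, FAP32 by 2.06 and the radial spoke gene RSP16 by 2.00. Of the flagella list's 279 members 7 differed upward in amiCYG12 and 0 downward (76 and 0 adjusted over the list alone), and the median was 0.63. In the antenna list, of 21 members 0 differed upward in amiCYG12 and 2 downward (0 and 9 adjusted over the list alone), with a median of -1.28. Of the fermentation list's 20 members 0 differed upward in amiCYG12 and 0 downward (2 and 0 adjusted over the list alone); HYDA1 had a difference of 2.16 and HYDA2 of 1.26, neither called. For the carbon concentrating mechanism, of 12 members 0 differed upward in amiCYG12 and 1 downward (0 and 3 adjusted over the list alone). With the spread taken from the 2 responses 31 loci remained, and with that of the 2 strain comparisons 38.

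From the standard incubation to anoxia the strains differed at 58 of 10686 loci, 17 upward and 41 downward in amiCYG12, and 20 of them exceeded the difference with the added 1 by over 1.5 times. LHCBM9 differed by -6.36 (standard error 1.25, q 0.000819), LCI34 (Cre03.g191300) by -3.36, HRP3 by -3.29 (standard error 0.574, q 0.000111) and GPM1 by -2.37. Upward differences were those of ROC59 with 3.57 (standard error 0.679, q 0.000539) and LAL2 with 3.36. CTH1 also differed upward (q 0.0410), ending at 7.86 FPKM in the wild type and 9.70 in amiCYG12 from 339 and 98.1. Of the fermentation list's 20 members 0 differed upward in amiCYG12 and 0 downward (the same adjusted over the list alone), and of the flagella list's 279 members 0 differed upward in amiCYG12 and 1 downward (0 and 3 adjusted over the list alone). In the cell cycle list, of 20 members 1 differed upward in amiCYG12 and 0 downward (5 and 0 adjusted over the list alone). With the spread taken from the 2 responses 27 loci remained.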

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

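The tests of a strain difference in each response were chosen after the group means had been seen, and so were 4 of the explanations weighed below: the authors' normalization for each of the 3 patterns, and regulated neighbours on chromosome 6. The other explanations and their limits had been written down before their values were computed.

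What set the following results apart is that the 2 strains' responses differed when the difference itself was tested. In the dark response 227 loci did so. The values come from the deposited log2 changes without a pseudocount. Upward in amiCYG12 were CAH1 with 3.30, BCS1 with 3.09, PPR9 with 2.52, ROC59 with 2.50 and CDKB1 with 2.41. Downward were LCI34 with -4.04, PHC18 with -3.86, HYDA2 with -2.61, SBD1, a selenium-binding protein gene, with -2.61, HYDG with -2.59 and HYDA1 with -2.38. In the anoxia response 75 loci differed: TRP5 with 3.76, FAP138 with 2.28, the flagellar gene CPZ with 2.15, FAP32 with 2.06 and RSP16 with 2.00 upward, and LHCBM9 with -5.00, MRPS29/CPL4 with -2.93, PSAI with -2.48, PPR9 with -2.36 and FTL1 with -2.21 downward. From standard to anoxia 58 loci differed: ROC59 with 3.57, LAL2 with 3.36 and CTH1 with 2.1 upward, and LHCBM9 with -6.36, LCI34 with -3.36, HRP3 with -3.29, CPLD53 with -2.63 and GPM1 with -2.37 downward. PHC18 lies on an unplaced scaffold and LHCBM9 has near-identical neighbours, so shared reads are possible for both; the cause was not tested. Any 2 of the 3 responses share the groups of 1 incubation, so a gene named in 2 of them is not 2 separate findings. PPR9 shares the dark aerated groups (11.3 FPKM in amiCYG12), and its difference from standard to anoxia was 0.16 (q 0.999); ROC59 and LCI34 share the standard groups and LHCBM9 the anoxic ones.

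The first pattern weighed is the higher level of chromosome 6 in amiCYG12. An extra copy of chromosome 6 would raise nearly all of its loci in all 3 incubations, and 89.3 percent of its 496 loci lay above the median of the other chromosomes in all 3, against 21.5 percent elsewhere. This share comes from the same values that define the pattern. It describes how widespread the shift is and cannot test its cause. The authors' normalization would move other chromosomes too, but the highest of the 16 others lay at -0.12 against 0.73 for chromosome 6. A few regulated neighbours would leave parts of the chromosome unchanged, but after the dark aerated incubation the lowest of the 15 blocks of 500 kb with at least 20 loci still lay at 0.47 and the highest at 0.97. The lowest of these blocks in the standard incubation was at 0.45, and the lowest of the 4 blocks with fewer loci, which held 2, at 0.40 after the dark aerated one. An extra copy is the candidate explanation these values leave standing, but no separate values tested it and DNA was not measured.

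The second pattern is that flagella genes were low and cell cycle genes high in amiCYG12 after the dark aerated incubation. Gene length bias is unlikely, since the lowest median of 10000 random lists matched on gene length and level was -0.26 against -1.08 for flagella. The authors' normalization would shift all loci, but the 10616 loci outside both lists had a median of -0.049. A larger share of dividing cells was weighed by 23 other mitosis and replication genes, picked by annotation text. Their median strain difference was 0.38, above the upper limit of 0.24 for random lists, with 10 called higher and 0 lower. As chromosome 6 is shifted as a whole, the 21 of them off it were also taken alone, after the result was seen: their median was 0.29, above an upper limit of 0.18 for random lists off chromosome 6, with 8 called higher and 0 lower. These genes share functions with the list that defined the pattern and were read in the same libraries. They cannot tell more dividing cells from a rise of such transcripts within cells, and do not bear on flagella genes. Core histones had a median of 0.013 in amiCYG12 from standard to dark aerated, with 0 of 7 called. Against the wild type in the dark aerated incubation the histone median was 0.87, with 4 higher and 0 lower. It already stood at 0.81 in the standard incubation, with 3 higher and 0 lower, so this difference is not particular to the dark aerated cells. Cell numbers or cell sizes were not used here, so a larger share of dividing cells remains a hypothesis.

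The third pattern is the higher level of fermentation genes in the wild type than in amiCYG12 after the dark aerated incubation. Oxygen shortage in the wild type's open beakers may have contributed, since the 576 loci outside the fermentation list that rose in amiCYG12 under anoxia against both other incubations had a median change of 0.22 in the wild type there, above the upper limit of 0.00045 for random lists, and 123 of them were called higher and 15 lower. Against a shortage as deep as in the sealed flasks stands the copper-linked group, of which 0 rose and 4 fell in that incubation, although 1 of the 4, CTH1, fell under anoxia as well. FDX5, HPD1, CYC6, GOX17 and RSE1 were among the 6 highest rises in both wild type contrasts of anoxia. The first 4 rose by 9.56, 6.06, 5.69 and 4.96 against dark aerated cells and by 9.24, 5.85, 5.53 and 4.33 against standard cells. None of these 4 was thus raised in the open beakers, while RSE1, with 3.97 and 4.25, went the other way. A high rank in both contrasts favours genes that were low in the open beakers, so these genes cannot argue against a shortage. HCP4, among the 6 highest against standard cells alone, had risen in the open beakers. The values cannot separate a loss of oxygen from other effects of the dark incubation. The authors' normalization is unlikely, as the other 10895 loci had a median strain difference of -0.060. Whether the knockdown of CYG12 or other traits of this transformant account for the difference cannot be told from 1 amiCYG12 line.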

How the results depend on the processing

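No paired analysis was possible because the table gives 1 value per group and no value per replicate. For the same reason the planned fits with only the groups compared, with a replicate block, with 1 library left out, without a trend, and the set test with an estimated correlation were not run. The calls do not depend on a pseudocount, but the printed log2 values do: with 5, 269 of 751 named gene values and 25 of 225 list medians moved towards 0, and with 0.1, 152 and 14 moved away from it, by at least the standard error recovered from the deposited p-value (for lists, the median of these errors). Without the filter on low values 8 of the 225 list medians moved by at least as much.

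A q threshold of 0.01 moved every count: 846, 573 and 1904 in the wild type (anoxia against dark aerated, dark aerated against standard, anoxia against standard), 1659, 806 and 1700 in amiCYG12, and 525, 1155 and 861 between the strains in the standard, dark aerated and anoxic incubation. Rescaling together with the recovered errors gave 707 calls, and those errors alone 780, for dark aerated against standard in the wild type. For the strains in the standard incubation the 2 gave 715 and 696, adjustment within the comparison 677 and leaving out chromosome 6 690; for dark aerated against standard in the wild type, adjustment within the comparison gave 765. Of these alternatives all but the rescaling were chosen after seeing the data. The recovered errors alone and the adjustment within the comparison use the same p-values, so they are not 2 separate checks.

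The counts of strain differences in the responses depended on the error used: 31 and 27 loci for the anoxia response and for anoxia against standard with the errors of the 2 responses, and 38 and 114 for the anoxia and the dark response with those of the 2 strain comparisons. One list turned its sign: flagella in the wild type, anoxia against standard, had a median of 0.13 after rescaling. None of the 751 named gene values turned its sign under the 4 alternatives run for them (rescaling, both pseudocounts, summed transcripts).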

Other observations

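These observations were made after the results were seen. Some plastid division genes were picked by name after MIND1 had stood out, without a fixed list or a test of the group. After the dark aerated incubation these were higher in amiCYG12 than in the wild type, FTSZ1 by 1.26, FTSZ2 by 0.79, MIND1 by 1.82, MINE1 by 1.61, MINE2 by 1.57 and ARC6 by 0.79. The differences of their dark responses, from the deposited log2 changes without the added 1, were 1.82 (q 0.0428), 1.69 (q 0.0641), 2.26 (q 0.00811), 2.50 (q 0.00886), 3.01 (q 0.0126) and 2.77 (q 0.0398), and that of FTSZ2 was not called. ARC6 was close to the floor, with 0.173 FPKM in the wild type and 1.03 in amiCYG12 there, and with the added 1 its difference was 0.86 and that of MINE2 1.55. In the standard incubation none of the 6 was called between the strains.

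Genes of iron uptake and storage were also picked after their values were seen. FEA1 had 671, 157 and 21.6 FPKM in the wild type and 120.4, 29.5 and 3.38 in amiCYG12, and the ferroxidase FOX1 had 54.9, 31.9 and 8.32 and 16.6, 16.1 and 5.49. From standard to anoxia FEA1 fell in the wild type and in amiCYG12, with -4.90 and -4.79, as did FOX1 with -2.58 and -1.44 and the ferritin gene FER1 with -1.55 and -1.54; this contrast includes the effect of darkness. The iron permease gene FTR1 fell with -1.43 in the wild type and had -0.34 in amiCYG12, not called. Against dark aerated wild type cells, anoxia gave FER1 and FTR1 values of -0.56 and -0.82, neither called, while both fell in amiCYG12, with -1.47 and -0.93. The metal transporter genes IRT2/ZIP10 and NRM1/NRAMP1 rose from standard to anoxia in both strains, IRT2/ZIP10 by 2.49 and 2.57, and NRM1/NRAMP1 from 6.59 to 31.5 FPKM in the wild type and from 4.81 to 20.7 in amiCYG12. In the standard incubation FEA1, FOX1, FTR1 and MSD3 were lower in amiCYG12, with -2.47, -1.67, -1.29 and -2.84.

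Some loci differed between the strains whatever the incubation. Of the 151 loci higher in amiCYG12 in all 3, 129 lay on chromosome 6, and of the 173 lower ones 6 did. FLU, a brake on chlorophyll synthesis, had 61.4, 27.8 and 9.39 FPKM in the wild type and 10.8, 6.91 and 2.15 in amiCYG12. COP3, a channelrhodopsin, had 73.7, 114 and 116 and 29.8, 22.0 and 40.2, and PHC18 84.5, 96.6 and 384 and 1.90, 0.150 and 5.26. The mating gene FUS1 was listed at 0 in all 6 groups.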
